A study of Homo sapiens and Trichophyton tonsurans and Trichophyton mentagrophytes with 30 samples.

How the data were processed

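The deposited values, TPM, were used as deposited; per the submitters' processing notes reads were aligned with HISAT2 and quantified with StringTie, with versions not given. The notes and labels give poly(A) selection, TruSeq libraries and paired-end Illumina sequencing. The name of the deposited human table refers to FPKM or RPKM, but its columns sum to between 988359.8 and 994102.8 per library, as TPM restricted to listed genes would, and the fungal columns sum to 1000000, so both were treated as TPM. No reads were aligned or counted again, and because TPM keeps no depth no test on counts was used. Gene symbols, identifiers and descriptions were those in the deposited tables. The human and fungal annotation versions are not given.

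All 30 libraries in 10 groups of 3 were matched to the deposited columns, with 0 unmapped columns. Human groups followed the treatment labels. Fungal groups followed the titles, because the treatment field reads the same for all 18 fungal libraries. The libraries, comparisons, gene lists and alternative settings were fixed before the data were examined, except where stated.

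Values were log2-transformed with a pseudocount of 1. Genes with at least 1 TPM in at least 3 libraries were tested, 13776 of 60666 human and 7636 of 7958 fungal genes. Linear models were fitted with limma (empirical Bayes moderation with an intensity trend) to all 12 human or all 18 fungal libraries in one fit, with 1 coefficient per group. Human contrasts set each co-culture against untreated cells and the co-cultures against one another; fungal contrasts set co-culture against fungus alone within each species and compared these differences between species. p-values were two-sided and adjusted with the Benjamini-Hochberg method over all genes tested in a contrast, with a threshold of 0.05; counts of calls with an absolute log2 fold change of at least 1 were kept beside them. Standard errors are those of limma.

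Gene lists, 34 human and 24 fungal, were written from textbook knowledge (human symbols) or as patterns in the deposited descriptions (fungal genes). Lists with at least 5 tested members were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over lists within a contrast. As alternatives, camera with an estimated correlation and the rotation test fry of limma, which asks whether a list moves away from 0 and not relative to other genes, were run. Counts of list members called are given over all genes tested and adjusted over the list alone.

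Genes named in the report followed a rule fixed before the data were examined. Among genes with an adjusted p under 0.05, a mean of at least 5 TPM in the higher group and all 3 libraries of 1 group above all 3 of the other, the 6 largest increases and decreases with a symbol or description were taken (3 each between co-cultures), with the 2 members of each list with the smallest p, or the member with the highest mean where none passed. Not all of them are printed. After the fungal table was seen, the description "hypothetical protein" was treated as no description, which left 2658 tested fungal genes without one. Genes chosen after their values were seen are marked.

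Alternative settings were a pseudocount of 0.1, a minimum of 5 TPM or no minimum, no intensity trend, only the 2 groups compared, a replicate block, leaving out each library in turn, and trimmed mean of M-values (TMM) scaling, coded here and applied to TPM. A length correction was added after results were seen: within each library a loess curve (span 0.5) of log2 TPM relative to the mean over libraries on log transcript length was subtracted for the 13669 tested human genes (99.2%) whose longest transcript is annotated in GENCODE release 29. TMM and leave-one-out for gene lists were also added then. A result was called weaker when its call ended, stronger when a call appeared, reversed when its direction changed, and a count was called moved when it changed more than 1.5-fold.

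Overlap of 2 responses was compared with the count for independent lists, N1 × N2 / N genes, and with 100 simulations in which unchanged groups shared the same controls. Chance groupings were examined by refitting each pair of groups over the 10 splits of its 6 libraries into 3 and 3, and by 100 relabellings within species for differences between species. Random draws of genes numbered 10000.

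The code was tested on simulated tables with known changes. It recovered 86% of changes of log2 size 1 and 100% of those of size 2, and called 5 unchanged human and 7 unchanged fungal genes in simulations of 13776 and 7636 genes. A simulated length trend without other changes gave 10437 calls before and 9 calls after the length correction. R 4.3.3, limma 3.58.1, the package data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9 were used.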

Results

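RNA was sequenced from HaCaT cells, an immortalised human keratinocyte line, kept for 24 h at 37 °C alone or with conidia of 1 of 3 dermatophyte fungi of the Trichophyton mentagrophytes complex: T. interdigitale, T. mentagrophytes or T. tonsurans. Conidia and cells were mixed at a multiplicity of infection of 1. The design asks how the keratinocytes respond to each fungus. Human transcripts were given for 12 libraries in 4 groups of 3, and fungal transcripts for 18 libraries in 6 groups of 3. All values are TPM, a unit normalised for transcript length and library total, which keep no sequencing depth, so the depth of each library is unknown. Between 20689 and 21521 human genes and between 7410 and 7651 fungal genes were above 0 per library. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Chromosomal positions are not printed because the genome build is not given in the sources used here.

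The fungal libraries were grouped by title. Libraries whose titles carry the prefix co_ (co_int, co_ment and co_ton) were taken as co-cultures and those without it (int, ment and ton) as fungus alone, although the treatment field describes co-culture for all 18. The library titled co_int_3 names T. tonsurans in its organism field. It was kept in co_int, where its mean correlation with the group lay among values of 0.986 to 0.990 (Pearson, across genes, log2 scale), against at most 0.859 between any co_int and any co_ton library.

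In HaCaT cells cultured with T. mentagrophytes, transcripts of inflammatory mediators rose. CXCL8 (ENSG00000169429), a chemokine that attracts neutrophils, averaged 1311 ± 241 TPM (SD, n = 3) against 9.75 ± 1.13 TPM in untreated cells, a log2 fold change of 6.92 with a standard error (SE) of 0.193. CSF2, which encodes the growth factor GM-CSF, averaged 98.6 ± 19.9 against 1.05 ± 0.507 TPM (log2 fold change 5.61). PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, averaged 161 ± 24.5 against 2.02 ± 0.370 TPM (5.74). In the list of cytokines and chemokines, 19 of 23 tested members rose and 2 fell, both over all genes tested and adjusted over the list alone; where 1 pair of counts is given for a list, both ways gave the same. The camera test of limma gave this list an adjusted p = 1.29e-15, and an adjusted p = 0.0613 with an estimated correlation. Among targets of the transcription factor NF-kB, 13 of 19 rose and 1 fell, including SOD2, the mitochondrial superoxide dismutase, at 220 ± 19.2 against 60.1 ± 3.21 TPM (camera adjusted p = 2.73e-07, and adjusted p = 0.490 with an estimated correlation).

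Immediate early genes and hypoxia-inducible genes rose in the same co-culture. ATF3 (ENSG00000162772), a stress-induced transcription factor, averaged 604 ± 35.2 TPM (n = 3) against 13.01 ± 0.580 TPM in untreated cells, a log2 fold change of 5.43. FOSB, a subunit of the transcription factor AP-1, averaged 204 ± 24.2 against 1.36 ± 0.163 TPM (6.44), and the nuclear receptor gene NR4A1 averaged 82.3 ± 1.06 against 2.33 ± 0.147 TPM (4.65). In the immediate early and AP-1 list 26 of 29 members rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 2.88e-24, and adjusted p = 0.151 with an estimated correlation). ANGPTL4 (ENSG00000167772), a secreted regulator of lipid metabolism that hypoxia induces, averaged 245 ± 12.5 against 1.78 ± 0.335 TPM (6.48). BNIP3, a mitophagy receptor, averaged 52.9 ± 3.79 against 2.86 ± 0.453 TPM (3.81), and ANKRD37 averaged 35.5 ± 1.70 against 3.11 ± 0.413 TPM (3.16). The glycolysis and hypoxia list had 27 of 30 members higher and 1 lower, over all genes and adjusted over the list alone (camera adjusted p = 3.77e-20, and adjusted p = 0.151 with an estimated correlation).

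Some host defence and matrix genes also rose with T. mentagrophytes. RNASE7, an antimicrobial ribonuclease of skin, averaged 45.8 ± 5.05 against 1.81 ± 0.252 TPM (log2 fold change 4.06, n = 3), and LCN2, which binds bacterial siderophores, averaged 2141 ± 330 against 482 ± 16.1 TPM (2.14). Of 10 antimicrobial peptide genes 6 rose and 2 fell (camera adjusted p = 0.00272, and adjusted p = 0.0774 with an estimated correlation). The collagenase gene MMP1 averaged 129 ± 39.3 against 2.57 ± 0.0252 TPM (5.14) and the stromelysin gene MMP10 averaged 36.7 ± 9.56 against 1.09 ± 0.220 TPM (4.14). In the list of matrix proteases and their inhibitors 16 of 25 rose and 6 fell (camera adjusted p = 1.29e-05, and adjusted p = 0.370 with an estimated correlation). GDF15, a stress cytokine, averaged 159 ± 4.14 against 12.4 ± 1.14 TPM, and CDKN1A, an inhibitor of cyclin-dependent kinases, averaged 117 ± 5.39 against 21.5 ± 1.71 TPM. Their list, the p53 targets, had 12 of 21 members higher and 5 lower, or 6 lower when adjusted over the list alone (camera adjusted p = 0.00542, and adjusted p = 0.673 with an estimated correlation). The amino acid stress list, 22 genes, had 11 higher and 5 lower, led by the regulator ATF4 at 395 ± 9.59 against 202 ± 2.51 TPM and by CHAC1, a glutathione-degrading enzyme, at 31.4 ± 3.73 against 9.44 ± 0.513 TPM. Its camera adjusted p = 0.0227 became an adjusted p = 0.803 with an estimated correlation, and 0.0550 without library 3 of the co-culture. Basal keratinocyte adhesion genes went up in 9 and down in 2 of 16 members (10 and 2 when adjusted over the list alone). The basal keratin KRT5 fell to 202 ± 10.99 from 823 ± 28.2 TPM (camera adjusted p = 0.00467, and adjusted p = 0.673 with an estimated correlation).

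Some respiratory chain, mitotic and keratin genes fell with T. mentagrophytes. COX8A, a cytochrome c oxidase subunit, averaged 438 ± 41.4 against 1167 ± 36.9 TPM (log2 fold change -1.42, n = 3), and NDUFS3, a complex I subunit, averaged 87.4 ± 1.36 against 169.5 ± 10.8 TPM (-0.95). Nuclear oxidative phosphorylation genes fell in 26 of 31 members, 27 when adjusted over the list alone, and rose in 1; the camera adjusted p = 3.59e-08 held as an adjusted p = 0.0269 with an estimated correlation. CCNB1, the mitotic cyclin B1, averaged 116 ± 1.84 against 367 ± 2.81 TPM (-1.66) and the mitotic kinesin gene KIF20A averaged 14.6 ± 3.80 against 84.7 ± 8.10 TPM (-2.48). In the mitosis list 20 of 28 members fell and 0 rose (camera adjusted p = 1.79e-06, and adjusted p = 0.662 with an estimated correlation). KRT13 (ENSG00000171401), a keratin of stratified epithelia, averaged 1276 ± 150 against 3836 ± 143 TPM (-1.59), and the wound keratin KRT6A averaged 47.5 ± 3.04 against 121 ± 5.01 TPM (-1.33). Of 9 wound-associated keratins 6 fell and 1 rose (camera adjusted p = 0.0222, adjusted p = 0.662 with an estimated correlation, 0.0740 after trimmed mean of M-values (TMM) scaling and 0.0897 after length correction). PSMB9 (ENSG00000240065) and PSMB10, subunits of the immunoproteasome that trims peptides for antigen presentation, fell by 2.15 and 1.46 on the log2 scale. The antigen presentation list as a whole had 4 of 19 members higher and 5 lower (camera adjusted p = 0.701). The largest decreases among genes at 5 TPM or more included ID1, an inhibitor of differentiation (-3.97), TNFSF10, the death ligand TRAIL (-3.17) and BCYRN1, a brain cytoplasmic RNA (-4.51).

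Interferon-stimulated genes went both ways with T. mentagrophytes. IFI27 rose to 167 ± 38.1 from 6.73 ± 1.44 TPM (n = 3), and OASL (ENSG00000135114), related to the antiviral oligoadenylate synthetases, fell to 26.4 ± 3.96 from 88.2 ± 6.21 TPM. Of 27 list members 5 rose and 13 fell, 14 when adjusted over the list alone (camera adjusted p = 0.193). EPHA2, a receptor of epithelial cells that binds fungal beta-glucan, rose to 30.1 ± 0.912 from 11.1 ± 1.51 TPM. The 10 tested genes of the fungal recognition list split into 2 higher and 4 lower, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.662). Epidermal differentiation genes rose in 1 and fell in 4 of 11 (camera adjusted p = 0.365). Cytosolic ribosomal protein genes rose in 8 and fell in 4 of 39, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.0805), with RPS2 lower at 3203 ± 215 against 5222 ± 396 TPM. Markers of other cell types did not move together. The fibroblast genes COL1A1 and FBLN1 averaged 0.820 ± 0.376 and 20.2 ± 3.003 TPM against 1.92 ± 0.360 and 33.3 ± 3.94 TPM, and both fell. For leukocytes, the macrophage protein CD68 rose to 40.5 ± 2.11 from 15.7 ± 2.49 TPM and the monocyte receptor CD14 fell to 1.18 ± 0.616 from 2.56 ± 0.559 TPM. The melanocyte factor MITF (3.84 ± 0.425 against 5.10 ± 1.11 TPM) and the endothelial cadherin CDH5 (8.48 ± 2.34 against 5.06 ± 1.01 TPM) did not pass the test. CDH5 passed after TMM scaling (log2 fold change 0.69) and length correction (0.74), with the replicate block (0.63), and without library 3 of the co-culture (0.81).

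**Figure D1:**
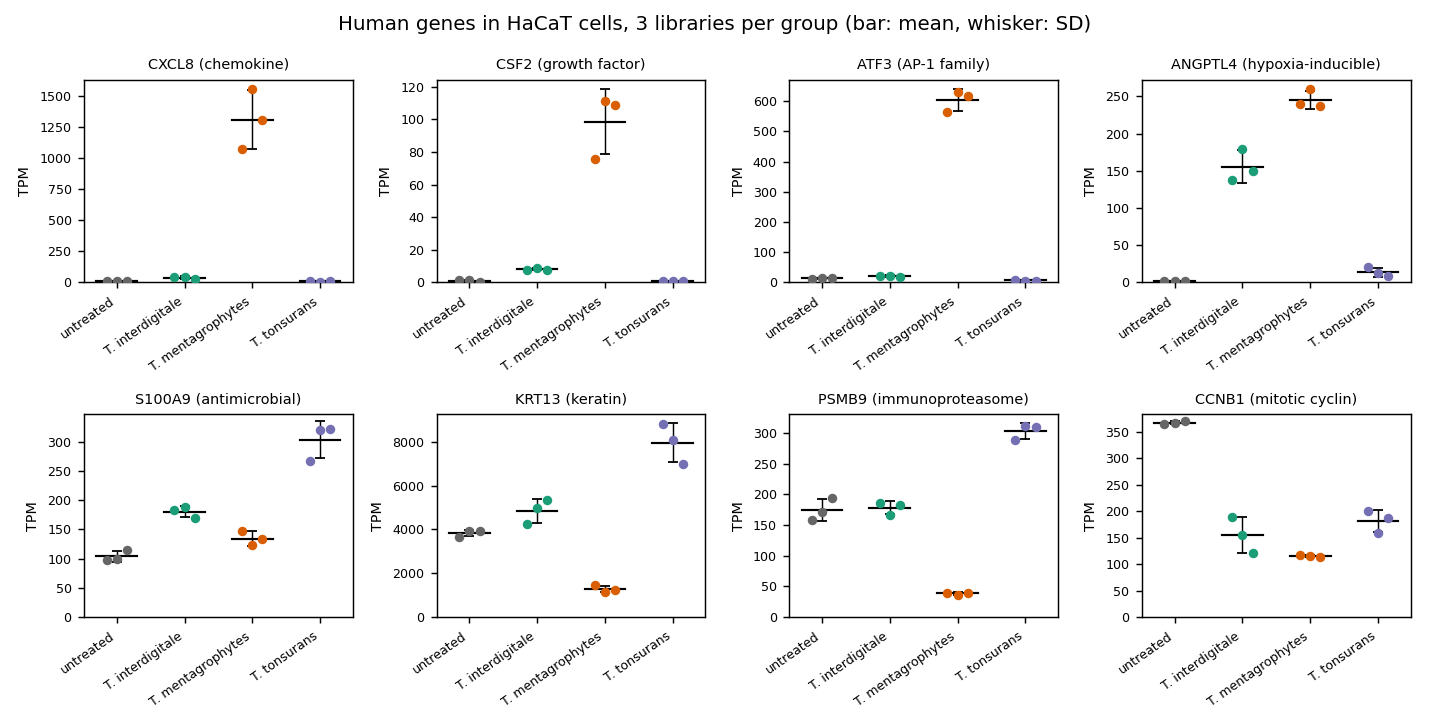
TPM (vertical axes, starting at 0) of 8 human genes in the 3 libraries of each of the 4 HaCaT groups; points are libraries, bars are means and whiskers are SD. CXCL8 averaged 1311 TPM with T. mentagrophytes against 38.7 with T. interdigitale, 7.32 with T. tonsurans and 9.75 in untreated cells, whereas PSMB9 averaged 38.5 TPM with T. mentagrophytes and 303 with T. tonsurans.

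Across all 13776 human genes tested, 2244 rose and 3832 fell with T. mentagrophytes (limma, Benjamini-Hochberg adjusted p under 0.05), 891 and 1133 of them by at least 2-fold. The genes named as changed above had limma adjusted p values up to 0.0214, the value of CD14, and the largest and list-leading ones had all 3 libraries of one group above all 3 of the other. TMM scaling, which moved the median log2 fold change of all genes from -0.12 to -0.03, gave 3063 higher and 3558 lower, and a correction for transcript length gave 3511 higher and 3697 lower, with 0 calls changing direction. The CD14 call ended without a filter on low values and without library 2 or 3 of the co-culture or library 2 of the untreated cells (limma adjusted p from 0.0616 to 0.0977). FBLN1 ended without the filter, without co-culture library 2 or untreated library 1 or 2 (0.0552 to 0.0750), and COL1A1 without co-culture library 2 (0.0653).

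With T. interdigitale, CA9 (ENSG00000107159), a carbonic anhydrase induced by hypoxia, averaged 114 ± 23.8 TPM (n = 3) against 12.3 ± 0.979 TPM in untreated cells, a log2 fold change of 3.08 (SE 0.214), and BNIP3 averaged 16.8 ± 1.55 against 2.86 ± 0.453 TPM (2.21). MMP1 averaged 29.9 ± 5.56 against 2.57 ± 0.0252 TPM (3.09) and MMP10 averaged 8.29 ± 2.12 against 1.09 ± 0.220 TPM (2.14). CXCL8 averaged 38.7 ± 8.43 against 9.75 ± 1.13 TPM (1.86) and CSF2 averaged 8.05 ± 0.612 against 1.05 ± 0.507 TPM (2.17). RPL13 (ENSG00000167526), a protein of the large ribosomal subunit, averaged 9660 ± 180 against 4962 ± 486 TPM (0.97). THBS1, the matrix protein thrombospondin 1, fell to 10.7 ± 3.54 from 132 ± 30.3 TPM (-3.52), and the desmosomal genes DSG2 and DSP changed by -3.50 and -3.39.

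This comparison carried a shift of the whole scale. The median log2 fold change of all genes was -0.72, and -0.02 after TMM scaling, so changes are best read relative to that median. limma called 1559 genes higher and 8375 lower (Benjamini-Hochberg adjusted p under 0.05), 425 and 5324 by at least 2-fold. TMM scaling gave 4667 higher and 4994 lower, and length correction gave 4484 and 4324. Of the original calls 6553 kept their direction and their side of the threshold with TMM and 5731 with length correction, under which 959 changed direction. Shorter genes gained relative to longer ones: the median log2 fold change was 0.10 for the 1370 genes with transcripts of 75 to 985 nt and -1.50 for the 1366 genes of 7177 to 43816 nt. Mitochondrially encoded genes held 5.53% ± 0.728 of the human TPM against 13.2% ± 0.839 in untreated cells, and cytosolic ribosomal protein genes 17.6% ± 0.613 against 11.4% ± 0.999 (n = 3).

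**Figure D2:**
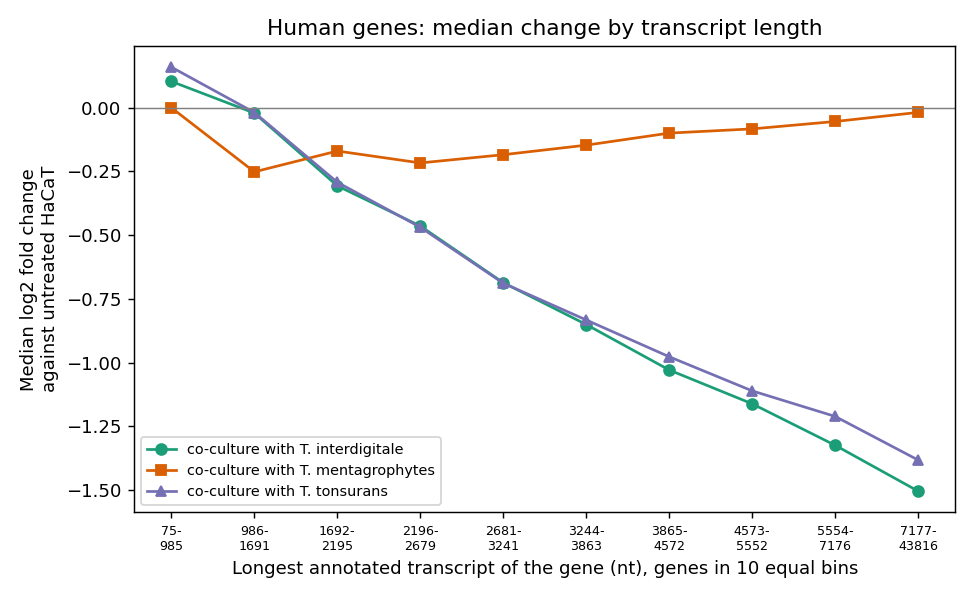
Median log2 fold change against untreated HaCaT cells (vertical axis) for human genes in 10 equal bins of longest annotated transcript in nt (horizontal axis), one line per co-culture. The lines for T. interdigitale and T. tonsurans go from 0.10 and 0.16 in the shortest bin to -1.50 and -1.38 in the longest, while the T. mentagrophytes line stays between -0.25 and 0.

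Gene lists in the T. interdigitale co-culture are given with both splits. Glycolysis and hypoxia genes had 12 of 30 members higher and 5 lower (25 and 0 after TMM scaling, 26 and 0 after length correction; camera adjusted p = 1.11e-08, and adjusted p = 0.570 with an estimated correlation). In the ribosomal protein list 28 of 39 rose and 2 fell, 3 when adjusted over the list alone (38 and 0 after TMM scaling), with RPS19 at 3791 ± 531 against 1633 ± 139 TPM (camera adjusted p = 1.58e-18, and adjusted p = 0.397 with an estimated correlation). The wound keratin list had 5 of 9 members higher and 1 lower (8 and 0 after TMM scaling, camera adjusted p = 0.000730, and adjusted p = 0.570 with an estimated correlation). Its member KRT17 averaged 20.04 ± 2.68 against 7.26 ± 1.86 TPM. KRT7, a simple epithelial keratin that the list also holds, averaged 4796 ± 548 against 3113 ± 104 TPM. Antimicrobial peptide genes rose in 5 and fell in 1 of 10 (9 and 0 after TMM scaling), among them the calprotectin subunit S100A9 (ENSG00000163220) at 181 ± 10.1 against 104 ± 9.52 TPM and the protease inhibitor SLPI at 305 ± 18.6 against 175 ± 28.9 TPM. Their camera adjusted p = 5.42e-05 held as an adjusted p = 0.0471 with an estimated correlation but was 0.138 after length correction. Antigen presentation genes rose in 5 and fell in 2 of 19 (4 and 2 over the list alone, 14 and 0 after TMM scaling), with PSMB10 at 169 ± 26.6 against 105 ± 4.72 TPM (camera adjusted p = 0.00255, and adjusted p = 0.570 with an estimated correlation).

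Several lists passed upward with T. interdigitale although their members split or fell, because camera compares them with all other genes. The immediate early and AP-1 list had 6 of 29 members higher and 6 lower with a median of -0.10, but 16 and 3 after TMM scaling and 20 and 3 after length correction (camera adjusted p = 0.000986 upward, and adjusted p = 0.783 with an estimated correlation). The early-response gene IER3 averaged 329 ± 16.1 against 115 ± 5.95 TPM and the AP-1 subunit JUND 123 ± 19.5 against 29.2 ± 7.47 TPM. Cytokine and chemokine genes split 5 and 5 of 23, 4 and 5 over the list alone, and 12 and 1 after TMM scaling (camera adjusted p = 0.00363 upward, adjusted p = 0.570 with an estimated correlation, and 0.158 after length correction). Matrix proteases split 6 and 9 of 25, or 16 and 5 after TMM scaling (camera adjusted p = 0.0157 upward, adjusted p = 0.783 with an estimated correlation, and 0.0706 after length correction). Nuclear oxidative phosphorylation genes split 10 and 12 of 31, or 24 and 3 after TMM scaling (camera adjusted p = 0.0138 upward, adjusted p = 0.397 with an estimated correlation, and 0.0712 after length correction). The medians of these 4 lists lay below 0 although the camera direction was up. Replication histones, a sign of RNA without a poly(A) tail, rose in 2 and fell in 2 of 10 (camera adjusted p = 0.0196, adjusted p = 0.570 with an estimated correlation, 0.210 after TMM scaling, 0.852 after length correction and 0.0617 without library 3 of the co-culture).

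Junction, cell cycle and mitochondrially encoded genes fell with T. interdigitale. Cell junction genes fell in 21 of 24 members and rose in 0, or fell in 16 and rose in 4 under either TMM scaling or length correction; the desmosomal genes PKP2 and DSG3 fell to 4.12 ± 1.17 from 38.0 ± 6.15 TPM and to 2.72 ± 0.595 from 26.2 ± 6.15 TPM (camera adjusted p = 0.00422, and adjusted p = 0.783 with an estimated correlation). In the mitosis list 26 of 28 fell and 0 rose, or 22 and 3 after TMM scaling. BUB1B (ENSG00000156970), a spindle checkpoint kinase, fell to 6 ± 0.805 from 51.5 ± 4.76 TPM, and NUSAP1, a spindle protein, to 12.2 ± 3.49 from 76.8 ± 5.22 TPM (camera adjusted p = 4.61e-05, and adjusted p = 0.783 with an estimated correlation). DNA replication genes fell in 26 and rose in 1 of 30 (19 and 8 after TMM scaling), including the polymerase gene POLA1 (-2.66) and the ribonucleotide reductase gene RRM1 (-1.89; camera adjusted p = 0.00534, adjusted p = 0.783 with an estimated correlation, and 0.105 after TMM scaling). Mitochondrially encoded genes fell in 12 of 13 (9, with 2 higher, after TMM scaling), with MT-ND4L at 1583 ± 355 against 10534 ± 2040 TPM and MT-ND5 at 394 ± 69.2 against 1492 ± 180 TPM (camera adjusted p = 0.0254, adjusted p = 0.783 with an estimated correlation, 0.142 after TMM scaling and 3.66e-05 after length correction). Interferon-stimulated genes rose in 3 and fell in 18 of 27, 9 and 14 after TMM scaling (camera adjusted p = 0.417). IFIT3, an antiviral protein, fell by 2.61 and OASL fell by 2.00. Fungal recognition genes rose in 1 and fell in 7 of 10, or 2 and 6 after TMM scaling (camera adjusted p = 0.628).

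With T. interdigitale, markers of other cell types went different ways. CD68 rose to 28.4 ± 2.27 from 15.7 ± 2.49 TPM and MITF fell to 0.393 ± 0.155 from 5.10 ± 1.11 TPM. FBLN1 (-0.56, but 0.30 after TMM scaling and 0.12 after length correction), COL1A1 (-0.96, but 0.40 after length correction) and CDH5 (-0.96, but 0.06 after length correction) turned direction with the correction and gave no stable call. FBLN1 also lost its call without the filter on low values and without co-culture library 1 or untreated library 1 or 2 (limma adjusted p from 0.0857 to 0.133). Among the genes named as changed in this co-culture the highest limma adjusted p was 0.0335, that of FBLN1.

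With T. tonsurans, S100A9 rose to 303 ± 31.0 TPM (n = 3) from 104 ± 9.52 TPM in untreated cells, a log2 fold change of 1.53 (SE 0.114), and SLPI rose to 450 ± 51.1 from 175 ± 28.9 TPM (1.36). Several keratin genes rose: KRT15 averaged 615 ± 11.8 against 263 ± 2.17 TPM, KRT13 averaged 7958 ± 898 against 3836 ± 143 TPM, and KRT19 averaged 2887 ± 303 against 1643 ± 109 TPM. The immunoproteasome genes PSMB9 and PSMB10 rose to 303 ± 12.9 from 175 ± 18.0 TPM and to 227 ± 20.2 from 105 ± 4.72 TPM. BUB1B fell to 9.15 ± 1.37 from 51.5 ± 4.76 TPM, THBS1 to 10.6 ± 6.40 from 132 ± 30.3 TPM (-3.62), and ANKRD1, a target of mechanical and TGF-beta signalling, to 1.55 ± 0.260 from 14.8 ± 0.830 TPM (-2.63).

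The T. tonsurans comparison carried a similar shift: the median log2 fold change of all genes was -0.68, and -0.04 after TMM scaling. limma called 1340 genes higher and 8426 lower (Benjamini-Hochberg adjusted p under 0.05), 306 and 4832 by at least 2-fold. TMM scaling gave 4255 and 4666 and length correction gave 3827 and 3870. With TMM 6004 calls were kept, and with length correction 5000 were kept and 770 changed direction. Median log2 fold changes ran from 0.16 in the shortest to -1.38 in the longest of 10 length bins. Mitochondrially encoded genes held 7.58% ± 1.98 and ribosomal protein genes 16.7% ± 1.57 of the human TPM (n = 3).

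Lists called upward with T. tonsurans included ribosomal proteins, 27 of 39 higher and 3 lower (38 and 0 after TMM scaling), with RPS9 at 5185 ± 632 against 2213 ± 348 TPM and RPS2 at 9419 ± 655 against 5222 ± 396 TPM (camera adjusted p = 8.31e-20, and adjusted p = 0.256 with an estimated correlation). Antigen presentation genes rose in 8 and fell in 2 of 19, or 16 and 0 after TMM scaling (camera adjusted p = 1.03e-06, and adjusted p = 0.256 with an estimated correlation). Antimicrobial peptide genes rose in 7 and fell in 2 of 10 (7 and 0 after TMM scaling); their camera adjusted p = 1.03e-06 held as an adjusted p = 0.0161 with an estimated correlation but was 0.0512 after length correction. Nuclear oxidative phosphorylation genes rose in 13 and fell in 10 of 31, or 26 and 1 after TMM scaling and 19 and 1 after length correction. COX5B, a cytochrome c oxidase subunit, rose to 1191 ± 239 from 543 ± 78.1 TPM, while the ATP synthase gene ATP5F1A, at 328 ± 43.3 against 632 ± 19.3 TPM (-0.95), turned to 0.22 after length correction. The camera adjusted p = 3.53e-06 of this list held as an adjusted p = 0.0338 with an estimated correlation. Wound keratins rose in 5 and fell in 2 of 9, or 6 and 2 over the list alone (camera adjusted p = 8.61e-05, and adjusted p = 0.303 with an estimated correlation).

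Further lists were called upward with T. tonsurans although no more members rose than fell, because the all-gene median was lower still. Interferon-stimulated genes split 8 and 10 of 27 (15 and 6 after TMM scaling; camera adjusted p = 0.0153, and adjusted p = 0.751 with an estimated correlation). Oxidative stress genes under the factor NRF2 split 6 and 11 of 26 (17 and 8 after TMM scaling; camera adjusted p = 0.0271, adjusted p = 0.751 with an estimated correlation, 0.0682 after TMM scaling and 0.430 after length correction). Epidermal differentiation genes split 3 and 4 of 11, 3 and 3 over the list alone (camera adjusted p = 0.0457, adjusted p = 0.751 with an estimated correlation, 0.128 after TMM scaling, 0.335 after length correction, 0.0519 with the replicate block, 0.0502 with a pseudocount of 0.1, and 0.0960 and 0.0579 without library 1 of the co-culture or library 3 of the untreated cells). Replication histones split 1 and 2 of 10 (camera adjusted p = 0.0457, adjusted p = 0.751 with an estimated correlation, 0.363 after TMM scaling, 0.777 after length correction, and 0.127 and 0.0926 without library 3 of the co-culture or library 1 of the untreated cells). The medians of these 4 lists were below 0.

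Mitosis genes fell in 27 of 28 members with T. tonsurans and all 28 when adjusted over the list alone, or fell in 17 and rose in 5 after TMM scaling, with the mitotic kinesin gene KIF23 at 15.0 ± 2.90 against 64.0 ± 10.04 TPM (camera adjusted p = 0.000372, and adjusted p = 0.751 with an estimated correlation). DNA replication genes fell in 24 of 30 and rose in 0 (15 and 6 after TMM scaling), among them POLA1 (-2.08) and the replication initiation gene MCM10 (-2.15; camera adjusted p = 0.00208, adjusted p = 0.751 with an estimated correlation, and 0.0687 after TMM scaling). TGF-beta and matrix genes fell in 17 of 19, or 15 with 2 higher after TMM scaling (camera adjusted p = 0.00376, and adjusted p = 0.751 with an estimated correlation). Junction genes fell in 20 and rose in 1 of 24 (16 and 4 after TMM scaling), with PKP2 (-2.43) and the beta-catenin gene CTNNB1 (-1.70; camera adjusted p = 0.0283, and adjusted p = 0.912 with an estimated correlation). Heat shock genes fell in 15 and rose in 1 of 17 (10 and 3 after TMM scaling), with the chaperones HSPD1 at 114 ± 12.8 against 407 ± 52.7 TPM and HSP90AB1 at 532 ± 77.1 against 1428 ± 86.7 TPM (camera adjusted p = 0.0364, adjusted p = 0.751 with an estimated correlation, 0.182 after TMM scaling and 0.0604 with the replicate block). Fatty acid synthesis genes fell in 12 of 13, or 9 with 1 higher after TMM scaling (camera adjusted p = 0.0326, adjusted p = 0.822 with an estimated correlation, 0.0541 after TMM scaling and 0.378 after length correction).

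Immediate early and AP-1 genes rose in 0 and fell in 19 of 29 with T. tonsurans, or 3 and 11 after TMM scaling (camera adjusted p = 0.546), with the phosphatase gene DUSP6 (-2.47) leading. Cytokine genes rose in 1 and fell in 7 of 23, or 6 and 3 after TMM scaling (camera adjusted p = 0.3), with IL1A (-1.16) among the decreases. Mitochondrially encoded genes fell in 11 of 13 (5, with 3 higher, after TMM scaling), with MT-ND4L (-2.31) and MT-ND5 (-1.54; camera adjusted p = 0.167, 0.0237 without library 1 of the co-culture and 8.04e-05 after length correction). Fungal recognition genes rose in 1 and fell in 7 of 10, or 2 and 4 after TMM scaling (camera adjusted p = 0.855), and EPHA2 fell to 3.65 ± 1.14 from 11.1 ± 1.51 TPM. MITF fell (-1.77). CD68 (0.30, but 1.08 after TMM scaling and 0.58 after length correction), CDH5 (-0.96, but -0.35 and -0.01) and COL1A1 (-0.70, but -0.26 and 0.54) were called or not depending on the scaling. Apart from RNA5S8, below, the highest limma adjusted p among genes named as changed was 0.00678, that of COL1A1.

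**Figure D3:**
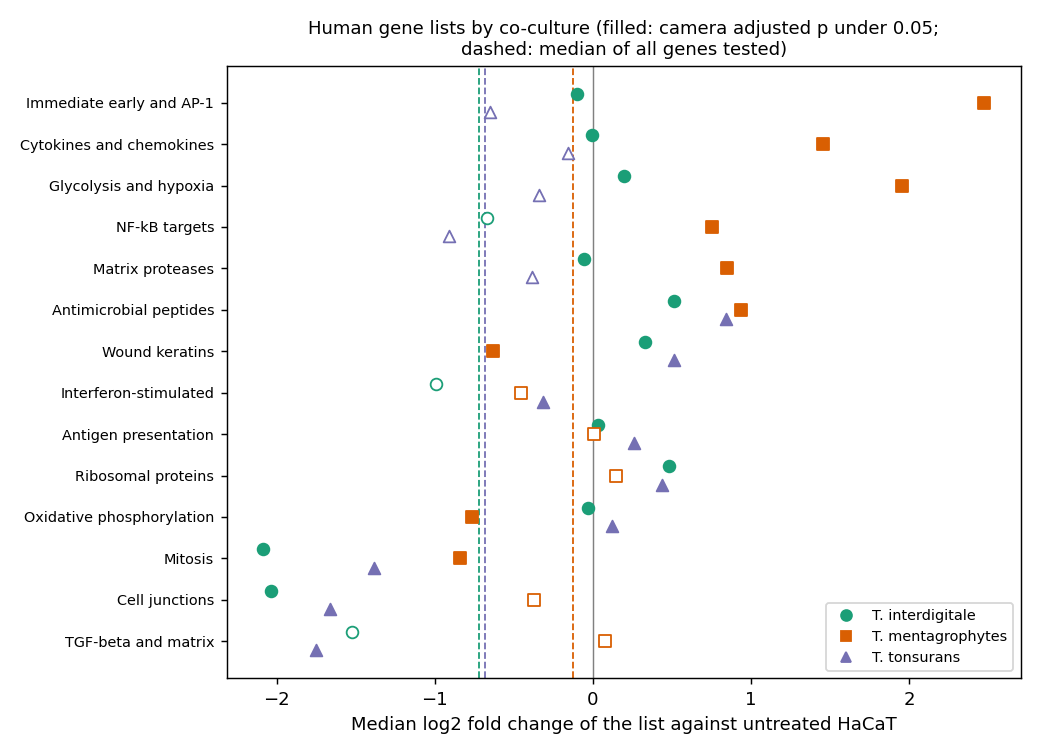
Median log2 fold change against untreated HaCaT cells (horizontal axis) of 14 gene lists (vertical axis) in the 3 co-cultures; filled symbols have a camera adjusted p under 0.05 and dashed lines mark the median of all genes tested, at -0.72, -0.12 and -0.68 for T. interdigitale, T. mentagrophytes and T. tonsurans. The immediate early and AP-1 list lies at 2.48 with T. mentagrophytes and at -0.10 with T. interdigitale, where its split turns from 6 higher and 6 lower to 16 and 3 after TMM scaling.

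Some short RNAs that poly(A) selection would not be aimed at headed the increases in the co-cultures. Apart from SNHG25, they were listed at 0 in all 3 untreated libraries, so no fold change is given. The Y RNA RNY1 was at 112, 197 and 376 TPM with T. interdigitale and at 161, 245 and 341 TPM with T. tonsurans. Of the 5S ribosomal RNA genes, which are near-identical copies, RNA5S16 was at 360, 408 and 192 TPM and RNA5S11 at 114, 160.5 and 476 TPM with T. mentagrophytes. With T. interdigitale RNA5S16 was at 182, 273 and 62.4 TPM and RNA5S3 at 185, 56.5 and 78.6 TPM. With T. tonsurans RNA5S1 was at 159, 205.5 and 77.1 TPM, RNA5S8 at 9.68, 135 and 112 TPM, and RPL21P75, a ribosomal protein pseudogene, at 5.57, 23.6 and 15.3 TPM. The small nucleolar RNA host gene SNHG25 was at 266 ± 34.2 TPM with T. interdigitale and 241 ± 205 TPM with T. tonsurans, against 1.67 ± 0.613 TPM. In limma, RNA5S8 lost its call without library 2 or 3 of the T. tonsurans co-culture or any 1 untreated library (adjusted p from 0.0596 to 0.0923), after length correction (0.0794) and without the filter on low values (0.131), and RNA5S3 lost its call without that filter (adjusted p = 0.0559).

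The co-cultures were also compared with one another. Between T. mentagrophytes and T. interdigitale, PTGS2 (161 ± 24.5 against 1.15 ± 0.382 TPM) and CXCL8 (1311 ± 241 against 38.7 ± 8.43 TPM) were higher with T. mentagrophytes, and SNHG25 (12.3 ± 1.74 against 266 ± 34.2 TPM) and BCYRN1 (11.7 ± 6.17 against 198 ± 5.56 TPM) were lower. Immediate early and AP-1 genes were higher in 27 of 29 and lower in 0 (camera adjusted p = 7.48e-07), cytokines higher in 20 and lower in 1 of 23 (0.000142), hypoxia genes higher in 25 and lower in 2 of 30 (0.0148), TGF-beta and matrix genes higher in 16 and lower in 1 of 19 (0.0253), and NF-kB targets higher in 13 and lower in 0 of 19 (0.0496). With an estimated correlation these adjusted p values were 0.886, 0.770, 0.886, 0.886 and 0.886. The NF-kB call also ended after TMM scaling (0.0724) and without library 1 of the T. interdigitale co-culture (0.0559). Oxidative phosphorylation genes were lower in 20 and higher in 3 of 31 (camera adjusted p = 7.94e-09, held as an adjusted p = 0.0185 with an estimated correlation), ribosomal proteins lower in 25 and higher in 7 of 39 (7.94e-09, and adjusted p = 0.886 with an estimated correlation), and wound keratins lower in 8 and higher in 0 of 9 (1.28e-05, and adjusted p = 0.524 with an estimated correlation). limma called 7618 genes higher and 2485 lower, 5319 and 5067 after TMM scaling and 4873 and 4951 after length correction, with 724 calls changing direction under the latter.

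Between T. mentagrophytes and T. tonsurans, CXCL8 (1311 ± 241 against 7.32 ± 1.60 TPM) and the AP-1 gene JUN (400.0 ± 24.8 against 2.66 ± 2.37 TPM) were higher with T. mentagrophytes, and LY6D, a keratinocyte surface protein (1.53 ± 0.903 against 62.3 ± 7.12 TPM), and BCYRN1 (11.7 ± 6.17 against 313 ± 80.2 TPM) were lower. Immediate early and AP-1 genes were higher in 28 of 29 and lower in 0 (camera adjusted p = 8.55e-09), hypoxia genes higher in 27 and lower in 1 of 30 (6.39e-06), and cytokines higher in 20 and lower in 2 of 23 (0.000163), each with an adjusted p = 0.724 with an estimated correlation. Oxidative phosphorylation genes were lower in 25 and higher in 3 of 31 (camera adjusted p = 1.02e-11, held as an adjusted p = 0.00643 with an estimated correlation). Ribosomal proteins were lower in 24 and higher in 6 of 39 (2.57e-07) and wound keratins lower in 7 and higher in 1 of 9 (0.000101), both with an adjusted p = 0.724 with an estimated correlation. limma called 7518 genes higher and 2669 lower, 5254 and 4995 after TMM scaling and 4885 and 4823 after length correction, with 542 calls changing direction under the latter.

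The T. tonsurans and T. interdigitale co-cultures lay closer together. OASL was higher with T. tonsurans (144 ± 10.9 against 21.4 ± 2.62 TPM, log2 fold change 2.70, n = 3). IL1RL1 (ENSG00000115602), the receptor of interleukin 33, was lower (0.220 ± 0.104 against 15.0 ± 4.06 TPM), as was ANGPTL4 (13.6 ± 6.25 against 156 ± 21.8 TPM). Hypoxia genes were lower in 17 of 30 and higher in 0, or 23 and 0 over the list alone (camera adjusted p = 4.36e-21, and adjusted p = 0.220 with an estimated correlation). Interferon-stimulated genes were higher in 11 of 27 and lower in 0, or 21 and 0 over the list alone (8.96e-13, and adjusted p = 0.204 with an estimated correlation). Immediate early and AP-1 genes were lower in 13 of 29, 14 over the list alone (8.96e-13, and adjusted p = 0.461 with an estimated correlation), mitosis genes higher in 10 of 28, 14 over the list alone (1.36e-06, and adjusted p = 0.678 with an estimated correlation), and cytokines higher in 2 and lower in 8 of 23, or 3 and 10 over the list alone (0.000341, and adjusted p = 0.461 with an estimated correlation). limma called 603 genes higher and 608 lower, 109 and 145 by at least 2-fold; 1146 and 1370 after TMM scaling and 1175 and 1378 after length correction. The counts depended on single libraries: 342 and 300 genes without library 2 and 234 and 389 without library 3 of the T. interdigitale co-culture, and 1182, 368 and 396 lower without library 1, 2 or 3 of the T. tonsurans co-culture.

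Responses of the co-cultures overlapped unequally. T. interdigitale and T. tonsurans shared 978 higher and 7598 lower genes of 13776, against 152 and 5123 for independent lists, with 63 in opposite directions. The covariance of their log2 fold changes was 0.757, against 0.0306 for simulated unchanged groups with the same controls but no shared technical shift. Pearson r was 0.907 against 0.461 across genes, which are not independent. After length correction they shared 3246 higher and 3316 lower (1255 and 1224 for independent lists), with a covariance of 0.492 against 0.0317. T. mentagrophytes shared 407 higher and 2286 lower genes with T. interdigitale (254 and 2330 for independent lists), with 1582 opposite and a covariance of 0.172 against 0.0330 (r 0.212 against 0.478); after length correction 1351 and 1246 (1152 and 1169), with 2120 opposite and a covariance of 0.153 against 0.0323. With T. tonsurans it shared 194 and 1930 (218 and 2344), with 1961 opposite and a covariance of 0.0169 against 0.0332 (r 0.0245 against 0.483); after length correction 789 and 852 (983 and 1047), with 2457 opposite and a covariance of -0.000830 against 0.0320. The 3 untreated libraries cannot form 2 sets of at least 2, so sharing them may add to any excess. A shared technical shift may too.

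Among fungal libraries of T. interdigitale, TMEN_6298, described as a pH-response transcription factor, averaged 783 ± 86.4 TPM in co_int (n = 3) against 129 ± 10.3 TPM in int, a log2 fold change of 2.59 (SE 0.391). A catalase (TMEN_4009), an enzyme that breaks down hydrogen peroxide, rose to 16.0 ± 3.89 from 1.26 ± 0.415 TPM, and 2 enzymes of ergosterol synthesis rose, the C-8 sterol isomerase TMEN_5219 to 602 ± 31.1 from 158 ± 12.6 TPM and the sterol reductase TMEN_4188 to 427 ± 33.7 from 155 ± 14.3 TPM. A heat shock 70 kDa protein (TMEN_3012) fell to 373 ± 6.89 from 1758 ± 192 TPM, a mitochondrial chaperone (TMEN_3998) to 74.95 ± 22.2 from 589 ± 103 TPM, and the alternative oxidase TMEN_4107, which lets electrons bypass part of the respiratory chain, to 121 ± 76.9 from 883 ± 209 TPM. Hexokinase (TMEN_5321) fell to 42.2 ± 5.32 from 168 ± 11.04 TPM and fructose-bisphosphate aldolase (TMEN_9567) to 440 ± 68.4 from 850 ± 10.2 TPM.

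Further increases in co_int included a non-heme chloroperoxidase (TMEN_7945, log2 fold change 2.80), a phosphate permease (TMEN_3745, 2.39), a cystathionine gamma-synthase (TMEN_8297, 0.45) and the polyketide synthases TMEN_7892 (0.97) and TMEN_5668 (0.63, limma adjusted p = 0.000880 and 0.101 with a pseudocount of 0.1). Further decreases included a ketoacid CoA transferase (TMEN_9462, -2.88), carbonic anhydrase (TMEN_8961, -2.41), an endochitinase (TMEN_9053, -1.77), a cytochrome P450 (TMEN_6472, -1.48) and a heat shock protein (TMEN_7374, -1.32). Among proteases, the subtilisin TMEN_6926 fell (-1.49) and the subtilisin TMEN_4057 rose (0.65, limma adjusted p = 0.0244, but 0.0793 with a pseudocount of 0.1, 0.0550 after TMM scaling and up to 0.0967 without co_int library 1 or 2 or int library 1 or 2). The hydrophobin TMEN_5238, at 8.81 ± 1.31 against 2.76 ± 1.23 TPM (1.42), had a limma adjusted p = 0.0425 that was lost under most settings (0.0613 after TMM scaling, 0.0628 with the replicate block, 0.220 with a pseudocount of 0.1, and 0.0759 to 0.135 without 1 library of co_int or library 1 or 2 of int).

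By list, ribosomal protein genes rose in 2 and fell in 7 of 122 in co_int, 0 and 0 adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.00282, and adjusted p = 0.978 with an estimated correlation); TMEN_9117 (-0.46) and TMEN_8544 (-0.57) led. Heat shock genes rose in 5 and fell in 12 of 45 (camera adjusted p = 0.0543, and 0.0353 after TMM scaling), and secondary metabolism genes rose in 11 and fell in 0 of 30 (0.0764, and 0.0353 after TMM scaling). Cell cycle and replication genes rose in 22 and fell in 6 of 47, 23 and 7 over the list alone (camera adjusted p = 0.165), the replication factor C gene TMEN_8001 by 1.13. Oxidative stress genes split 16 and 9 of 52 (16 and 12 over the list alone, 9 and 13 after TMM scaling; 0.961), glycolysis 5 and 7 of 30 (8 and 9 over the list alone; 0.183), ergosterol 6 and 4 of 38 (0.545; 4 and 10 after TMM scaling), subtilisins 1 and 1 of 12 (0.961) and metalloproteases 0 and 0 of 6 (0.474), where TMEN_5394 was highest at 18.9 ± 0.846 against 17.3 ± 2.79 TPM. limma called 1391 of 7636 genes higher and 796 lower (Benjamini-Hochberg adjusted p under 0.05), 234 and 159 by at least 2-fold, with a median of 0.11 (0.01 after TMM scaling, which gave 1030 and 1102). Only the 6 libraries of this fungus gave 2772 and 1645, and leaving out co_int library 1 gave 814 and 512, co_int library 2 918 higher, int library 2 864 higher, and int library 3 866 and 500.

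In T. mentagrophytes, ribosomal protein genes rose and cell wall and oxidative stress genes fell in co_ment relative to ment. The ribosomal protein genes TMEN_4362 and TMEN_2945 rose to 5097 ± 219 from 2959 ± 546 TPM (log2 fold change 0.80, SE 0.0970, n = 3) and to 4912 ± 479 from 3031 ± 354 TPM. Catalase (TMEN_4009) fell to 45.9 ± 8.44 from 414 ± 94.2 TPM (-3.13) and a thaumatin-like protein (TMEN_6037) to 63.2 ± 27.2 from 709 ± 311 TPM (-3.43). The major facilitator transporter TMEN_2533 fell to 1.90 ± 0.572 from 51.3 ± 8.71 TPM (-4.18), and the WSC domain protein TMEN_2622 to 7.82 ± 3.27 from 119 ± 59.2 TPM (-3.68). Hexokinase (TMEN_5321) rose to 185 ± 31.4 from 78.2 ± 5.64 TPM and a ribonuclease (TMEN_3081) to 63.5 ± 11.9 from 5.87 ± 1.77 TPM.

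Ribosomal protein genes rose in 106 and fell in 0 of 122 in co_ment, or 109 and 0 over the list alone (116 and 0 after TMM scaling; camera adjusted p = 2.31e-51, and adjusted p = 0.216 with an estimated correlation). Their share of the fungal TPM was 31.3% ± 1.84 in co_ment against 25%, 16% and 16.5% in the 3 ment libraries, so that ment library 1 stood apart; without it the camera adjusted p was 2.14e-61. Mitochondrial respiration genes rose in 24 and fell in 2 of 60, or 23 and 2 over the list alone (44 and 0 after TMM scaling), such as the cytochrome c oxidase gene TMEN_2668 (0.47), while the alternative NADH dehydrogenase TMEN_7298 fell (-0.55, but limma adjusted p = 0.0776 after TMM scaling; list camera adjusted p = 7.05e-12, and adjusted p = 0.106 with an estimated correlation). Heat shock genes split 14 and 13 of 45, 18 and 7 after TMM scaling, with TMEN_7374 at 244 ± 45.4 against 134 ± 5.43 TPM and the chaperone TMEN_3242 at 82.6 ± 15.6 against 178 ± 27.9 TPM; the median was -0.13 although the camera direction was up (adjusted p = 0.00765, and adjusted p = 0.106 with an estimated correlation). Oxidative stress genes fell in 35 and rose in 3 of 52 (28 and 5 after TMM scaling), for example the glutathione transferase TMEN_3348 (-1.57; camera adjusted p = 0.00782, and adjusted p = 0.930 with an estimated correlation). Cell wall genes fell in 35 and rose in 1 of 48 (23 and 4 after TMM scaling), with a beta-glucan-binding protein (TMEN_7829, -1.90) and a chitin synthase (TMEN_8221, -1.02; camera adjusted p = 0.00910, and adjusted p = 0.930 with an estimated correlation). Exopeptidases fell in 29 and rose in 1 of 42, or 31 and 1 over the list alone (16 and 4 after TMM scaling), with the carboxypeptidase TMEN_3903 at 2.79 ± 0.609 against 16.3 ± 2.20 TPM and a vacuolar aminopeptidase (TMEN_6367) at 79.9 ± 11.2 against 203 ± 41.5 TPM (camera adjusted p = 0.0328, and adjusted p = 0.930 with an estimated correlation). The exopeptidase call ended without co_ment library 2 (0.0659), ment library 2 (0.115) or ment library 3 (0.0601).

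The endoprotease lists of co_ment did not pass. Subtilisins fell in 5 and rose in 0 of 12, 4 and 0 over the list alone (camera adjusted p = 0.886), among them TMEN_3132 (-1.38) and TMEN_6926 (-0.93), and aspartic proteases fell in 5 and rose in 0 of 8 (0.238), among them TMEN_8721 (-1.97) and TMEN_5093 (-1.56). Metalloproteases fell in 1 of 6 (0.801) and cell cycle genes rose in 5 and fell in 29 of 47 (0.701; 8 and 12 after TMM scaling). The hydrophobin TMEN_5238 (3.84 ± 1.82 against 2.37 ± 1.69 TPM) did not pass. Other large changes were a transporter (TMEN_7796, -3.74), an RNA-binding protein (TMEN_9234, 2.67), a lysine methyltransferase (TMEN_6199, 2.48) and the arabinitol dehydrogenase TMEN_4911 (2.23). The arabinitol dehydrogenase TMEN_2920 was at 331, 185 and 116 TPM against 0, 59.6 and 74.3 TPM, and the RNA polymerase subunit gene TMEN_7027 at 57.7, 67.5 and 126 TPM against 37.4, 0 and 12.2 TPM, and the call of TMEN_7027 ended without co_ment library 2 or 3 or ment library 2 (limma adjusted p from 0.0633 to 0.214). With only the 6 libraries of this fungus TMEN_2920, TMEN_7027, TMEN_9234, TMEN_6199, TMEN_4911, TMEN_7796 and TMEN_3132 lost their calls (limma adjusted p from 0.0512 to 0.157).

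limma called 855 of 7636 fungal genes higher and 3607 lower in co_ment (Benjamini-Hochberg adjusted p under 0.05), 240 and 933 by at least 2-fold. The median log2 fold change was -0.37, and -0.11 after TMM scaling, which gave 1519 and 2077. With only the 6 libraries of this fungus the counts were 106 and 668, and without ment library 1 they were 1174 and 4107.

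In T. tonsurans, 2 siderophore transporters fell and thioredoxin reductase, cytochrome c peroxidase and 2 succinate dehydrogenase subunits rose in co_ton relative to ton. The siderophore iron transporters TMEN_9412 and TMEN_2691 fell to 21.3 ± 5.68 from 264 ± 59.5 TPM (log2 fold change -3.57, SE 0.425, n = 3) and to 44.8 ± 5.77 from 122 ± 13.01 TPM (-1.43). Thioredoxin reductase (TMEN_2966), which keeps protein thiols reduced, rose to 2391 ± 176 from 357 ± 41.7 TPM (2.74), and cytochrome c peroxidase (TMEN_5220), a heme enzyme of mitochondria, to 1186 ± 27.0 from 265 ± 25.9 TPM (2.16). The pH-response factor TMEN_6298 rose to 134 ± 8.94 from 16.7 ± 1.36 TPM (2.94). Succinate dehydrogenase subunits rose, TMEN_4631 to 385 ± 5.96 from 171 ± 1.58 TPM and TMEN_5852 to 363 ± 12.5 from 184 ± 4.78 TPM.

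By list, ribosomal protein genes rose in 36 and fell in 1 of 122 in co_ton, 42 and 1 over the list alone, with TMEN_6591 (0.65) and TMEN_4362 (0.52) leading (camera adjusted p = 2.44e-06, and adjusted p = 0.959 with an estimated correlation). Respiration genes rose in 16 and fell in 3 of 60, 17 and 3 over the list alone (camera adjusted p = 0.000775, and adjusted p = 0.959 with an estimated correlation). Iron and siderophore genes as a list did not pass, with 1 higher and 6 lower of 16, 2 and 7 over the list alone (0.283). Oxidative stress genes rose in 6 and fell in 13 of 52, 6 and 14 over the list alone (camera adjusted p = 0.316), subtilisins rose in 1 and fell in 3 of 12, 1 and 4 over the list alone (0.559), among them TMEN_9832 (0.83) and TMEN_8365 (-0.70), and metalloproteases changed in 0 of 6 (0.664), with TMEN_5394 at 57.7 ± 0.285 against 63.8 ± 1.21 TPM. The carboxypeptidases TMEN_3903 and TMEN_9079 rose by 1.93 and 1.07, and the aspartic protease TMEN_8721 fell by 1.63. Other increases were an aminotransferase (TMEN_6313, 2.47), a cytochrome P450 (TMEN_6472, 2.16) and a polyketide synthase (TMEN_6315, 1.71). Other decreases were a threonine aldolase (TMEN_7956, -3.61), the transporter TMEN_2533 (-2.24) and a cystathionine gamma-synthase (TMEN_8297, -0.49). At 0 in co_ton were the ribosomal protein L39 gene TMEN_3740 (3931, 2939 and 3652 TPM in ton) and secreted protein TMEN_2061 (1378, 1140, 1444). So were the transfer RNA genes TMEN_20091 (295, 348, 307) and TMEN_20047 (43.9, 192, 63.6). Whether these zeros are failed estimates was not tested. limma called 861 of 7636 genes higher and 862 lower, 119 and 198 by at least 2-fold (949 and 948 after TMM scaling, 1445 and 1425 with only the 6 libraries of this fungus, and 547 higher without ton library 3).

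**Figure D4:**
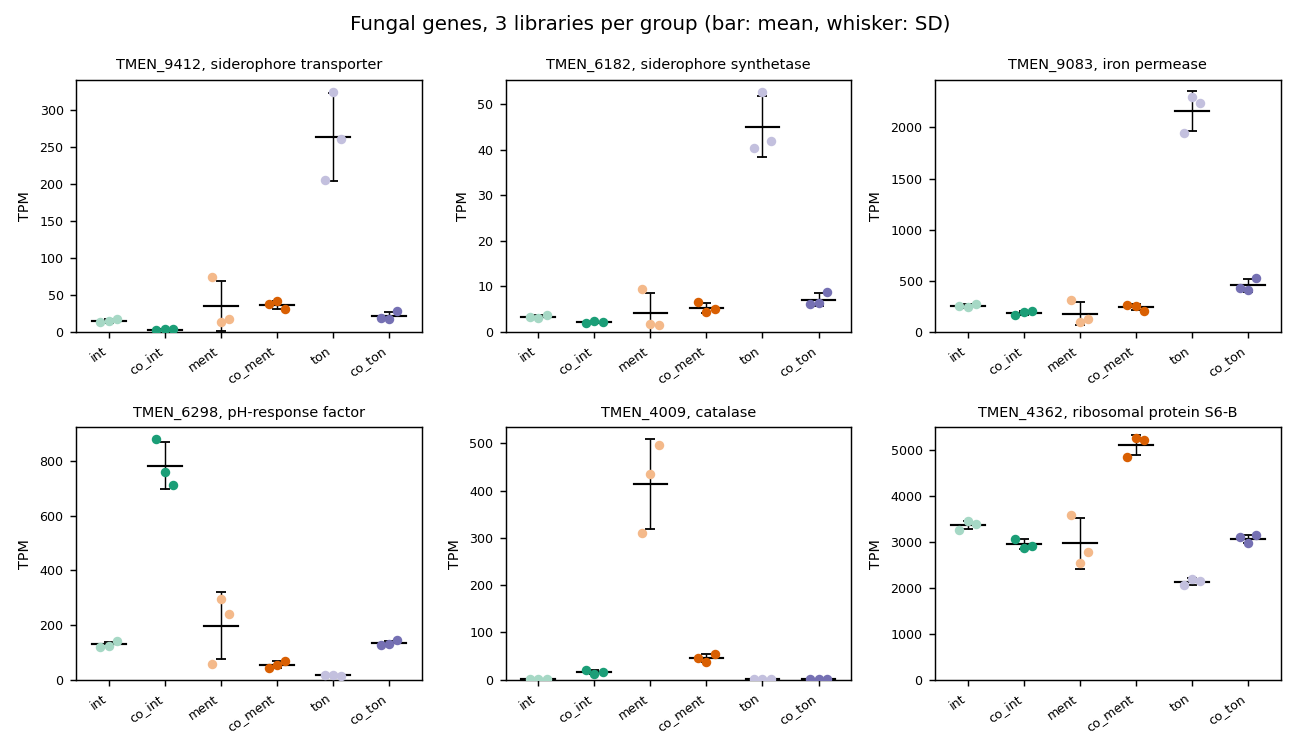
TPM (vertical axes, starting at 0) of 6 fungal genes in the 3 libraries of each of the 6 title groups; points are libraries, bars are means and whiskers are SD. The siderophore transporter TMEN_9412 averaged 264 TPM in ton and 21.3 in co_ton, and catalase TMEN_4009 averaged 414 TPM in ment and 45.9 in co_ment.

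The difference between co-culture and fungus alone was itself compared between the species. Relative to T. interdigitale, T. mentagrophytes had 901 genes with a higher and 3446 with a lower log2 fold change (limma, Benjamini-Hochberg adjusted p under 0.05; 1527 and 1977 after TMM scaling). Ribosomal protein genes were higher in 95 and lower in 1 of 122, 99 and 1 over the list alone and 105 and 1 after TMM scaling (camera adjusted p = 5.78e-39), respiration genes higher in 21 and lower in 4 of 60, 19 and 3 over the list alone and 42 and 0 after TMM scaling (1.75e-09), and heat shock genes higher in 14 and lower in 12 of 45 (0.00110, with a median of -0.05; 19 and 5 with a median of 0.37 after TMM scaling), with adjusted p = 0.390, 0.199 and 0.0723 with an estimated correlation. T. tonsurans relative to T. interdigitale had 816 higher and 1246 lower (1039 and 1097 after TMM scaling), with ribosomal proteins higher in 40 and lower in 2, 41 and 2 over the list alone (camera adjusted p = 4.88e-09) and respiration genes higher in 19 and lower in 7, 20 and 9 over the list alone (0.000336), both with an adjusted p = 0.999 with an estimated correlation. T. mentagrophytes relative to T. tonsurans had 496 higher and 2262 lower (985 and 1231 after TMM scaling; 1024 higher without ment library 1 and 329 higher without ton library 3). There ribosomal proteins were higher in 31 and lower in 0, 10 and 0 over the list alone and 63 and 0 after TMM scaling (camera adjusted p = 2.38e-25), exopeptidases lower in 26 and higher in 0 of 42, 27 and 0 over the list alone and 15 and 1 after TMM scaling (0.00427) and respiration genes higher in 3 and lower in 9 (3 and 8 over the list alone, 0.0274 upward; 16 and 1 after TMM scaling), each with an adjusted p = 0.789 with an estimated correlation. The respiration call ended without co_ment library 2 (0.0832), co_ton library 2 (0.0824), ment library 2 (0.144) or ton library 2 (0.0537).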

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

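The limma contrasts, splits and relabellings were chosen before the data were examined, the tests of length, short RNAs and ment_1 only after results were seen. Differences between species were tested in limma as the difference itself.

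Between co-cultures, 10103 human genes differed between T. mentagrophytes and T. interdigitale, 1211 between T. tonsurans and T. interdigitale, and 10187 between T. mentagrophytes and T. tonsurans (limma, Benjamini-Hochberg adjusted p under 0.05). Over the 10 splits of 6 libraries into 3 and 3, only the real one (1 of 10) reached these counts, with at most 1, 2 and 3 genes in any other. The same held for each co-culture against untreated cells, with 9934 genes for T. interdigitale (at most 0 otherwise), 6076 for T. mentagrophytes (3) and 9766 for T. tonsurans (2), and for fungi in co-culture against alone, with 2187 genes for T. interdigitale (1), 4462 for T. mentagrophytes (3042) and 1723 for T. tonsurans (2). With 10 splits a share under 0.05 cannot be reached.

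For fungal responses, 4347 genes differed between T. mentagrophytes and T. interdigitale, 2062 between T. tonsurans and T. interdigitale, and 2758 between T. mentagrophytes and T. tonsurans. Spread was pooled over groups, but r was as low as 0.937 within ment and at least 0.977 within others. Of 100 relabellings within species, 1, 1 and 2 gave as many, the real labels included. Other labels gave at most 2471, 1920 and 3699, so for the last pair 1 other labelling gave more genes. Relabellings mix the groups in the same way as the splits.

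Genes named here were chosen for opposite directions, so their p values are no fresh test. The log2 fold change of PSMB10 was lower with T. mentagrophytes than with T. interdigitale (-2.14, limma adjusted p = 3.69e-08). Between T. mentagrophytes and T. tonsurans the differences were -2.57 for PSMB10 (limma adjusted p = 4.29e-09), -2.95 for PSMB9 (2.18e-10), -2.64 for KRT13 (1.4e-09), -1.56 for RPS2 (2.17e-08) and 2.77 for EPHA2 (7.41e-08). In the fungi, the catalase TMEN_4009 differed by -6.03 between T. mentagrophytes and T. interdigitale (limma adjusted p = 2.43e-09), the hexokinase TMEN_5321 by 3.19 (8.24e-09) and the heat shock protein TMEN_7374 by 2.16 (3.04e-07). The cytochrome P450 TMEN_6472 differed by 3.63 (2.63e-06) and the cystathionine gamma-synthase TMEN_8297 by -0.94 (0.000214) between T. tonsurans and T. interdigitale, and the carboxypeptidase TMEN_3903 by -4.13 between T. mentagrophytes and T. tonsurans (3.97e-09).

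The fall of log2 fold changes with transcript length with T. interdigitale and T. tonsurans was weighed against a technical origin. A larger share taken by a few abundant genes would lower short and long genes alike, but genes at 20 TPM or more differed by -1.78 between the longest and shortest bins in both co-cultures (95% bootstrap interval -1.93 to -1.62 and -1.92 to -1.65), against 0.22 with T. mentagrophytes. RNA integrity or library preparation could give the trend, and so could a change of transcript lengths in the cells. Over all genes with a length, the difference between these bins varied by 0.521 among the 3 untreated libraries. The labels give no RNA quality, so these 2 stay open.

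Short RNAs listed at 0 in untreated cells were weighed next. Fungal reads placed on human genes would not raise RNAs that fungi lack. Yet 3 of 3 such RNAs tested were called higher in at least 1 co-culture. RNY1 and RNY3 belong to this pattern, but RN7SK (65.8, 77.4 and 81.8 TPM in untreated cells) does not. For the 5S genes, 10 of 17 were called higher, and fungal reads may still add to those. Of genes at 0 in 1 library and at 50 TPM or more in another, 94.1% were shorter than 300 nt, against 1.41% of all tested genes, which is consistent with failed estimates for short genes. No biological explanation was tested for this pattern.

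The library ment_1 lay near the co_ment libraries. Its mean correlation across genes was 0.970 with co_ment and 0.946 with the other ment libraries, and it stood at position 0.641 between those ment libraries (0) and co_ment (1), where co_ment library 1 stood at 0.766. A swap with a co_ment library would leave 1 co_ment library closer to ment, but each was closer to the rest of co_ment, by at least 0.0437. A wrongly named library from outside, or a culture at an intermediate state, could not be told apart.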

How the results depend on the processing

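The length correction for genes, and TMM scaling and leave-one-out for gene lists, were added after results were seen. Depth is unknown for TPM, so its limits could not be examined. Where no reason is given, the cause was not tested.

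A pseudocount of 0.1, a minimum of 5 TPM and limma without the trend left all 24 counts of called genes within 1.5-fold of the values reported. TMM scaling moved 14 of 24. It gave 4667 higher and 4994 lower with T. interdigitale, 4255 and 4666 with T. tonsurans, 5067 lower between T. mentagrophytes and T. interdigitale, 1146 and 1370 between T. tonsurans and T. interdigitale, and 4995 lower between T. mentagrophytes and T. tonsurans. In the fungi it gave 1519 and 2077 in co_ment, and 1527 and 1977 for the T. mentagrophytes against T. interdigitale difference and 985 and 1231 for T. mentagrophytes against T. tonsurans. Length correction gave 4484 and 4324 with T. interdigitale, 3511 higher with T. mentagrophytes, 3827 and 3870 with T. tonsurans, 4873 and 4951 between T. mentagrophytes and T. interdigitale, 1175 and 1378 between T. tonsurans and T. interdigitale, and 4885 and 4823 between T. mentagrophytes and T. tonsurans.

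With only the 2 groups compared, counts were 244 and 261 between T. tonsurans and T. interdigitale, 2772 and 1645 in co_int, 106 and 668 in co_ment, and 1445 and 1425 in co_ton. Without a filter, more genes were tested and 364 were higher between T. tonsurans and T. interdigitale.

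The replicate block gave 993 higher in that comparison and moved no other count. Deviations of same-number libraries did not all correlate above 0.1, so the block stayed an alternative. Yet in each co-culture libraries 1 and 3, not 2, matched the untreated library of their number best, so pairing stays possible.

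Leaving out 1 library moved 16 of 180 counts of called genes, assuming that remaining libraries vary alike. Ranges over libraries were 234 to 540 higher and 300 to 1182 lower between T. tonsurans and T. interdigitale, 814 to 954 higher and 500 to 577 lower in co_int, 547 to 665 higher in co_ton, and 329 to 1024 higher for the T. mentagrophytes against T. tonsurans difference. Lists passing ranged from 1 to 2 in co_int and from 2 to 5 in that last difference.

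The number of lists passing depended on the list test. With an estimated correlation it was 1 with T. interdigitale, 1 with T. mentagrophytes, 2 with T. tonsurans, 1, 0 and 1 between co-cultures (T. mentagrophytes against T. interdigitale, T. tonsurans against T. interdigitale, T. mentagrophytes against T. tonsurans), and 0 in each fungal comparison. With fry it was 24 with T. interdigitale, 26 with T. tonsurans, 26, 6 and 27 between co-cultures in the same order, 2 in co_int, 20 in co_ment, and 20, 4 and 15 for the differences between species. Fry tests movement away from 0, so the shift of the scale enters it. TMM scaling gave 5 lists in co_int and 5 for T. mentagrophytes against T. tonsurans, and length correction 9 lists with T. interdigitale.

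Directions turned in 15 cases. With fry these were matrix proteases (adjusted p = 0.474) and oxidative phosphorylation (0.0013) with T. interdigitale; interferon-stimulated genes (0.115), oxidative stress (0.0412), epidermal differentiation (0.625), replication histones (0.706) and cytokines (0.0111) with T. tonsurans; and respiration for T. mentagrophytes against T. tonsurans (0.764). With length correction COL1A1 (0.40), FBLN1 (0.12) and CDH5 (0.0583) with T. interdigitale and ATP5F1A (0.22) and COL1A1 (0.54) with T. tonsurans turned upward, and replication histones with T. tonsurans turned downward (adjusted p = 0.777). With TMM scaling FBLN1 turned to 0.30 with T. interdigitale.

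Among named genes and lists, TMM scaling kept 324 results, weakened 18 below the threshold and brought 4 past it. Length correction kept 200, weakened 12 and brought 3 past it, and leaving out 1 library kept 2085 of its results and weakened 41. The estimated correlation kept 31 list results and ended 71.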

Other observations

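In co_ment, ribosome biogenesis genes, not a list fixed beforehand nor tested with camera, rose with the ribosomal proteins. Of 81 tested, 52 rose and 2 fell, with a median log2 fold change of 0.90 (68 and 0 after TMM scaling, 70 and 3 with a median of 1.45 without ment library 1). In co_int the same genes rose in 7 and fell in 1, and in co_ton they rose in 1 and fell in 4. In co_ton 4 more genes of the iron and siderophore list fell, a ferrichrome siderophore synthetase (TMEN_6182, log2 fold change -2.52), a plasma membrane iron permease (TMEN_9083, -2.25), a ferric reductase (TMEN_9950, -2.36) and a ferric/cupric reductase (TMEN_3520, -0.46), all chosen after their values were seen.

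The tests below, and their iron-using list, were chosen only after the results were seen. Faster division of the fungal cells in co_ment might explain the ribosome genes, and would raise cell cycle and replication genes too. Their median after TMM scaling was -0.15 (95% bootstrap interval -0.22 to -0.04), close to the -0.11 of all genes, with 8 of 47 higher and 12 lower, so faster division was neither excluded nor supported.

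More iron available to the fungus in co_ton could lower uptake genes and raise genes of iron-using proteins. Of 77 iron-using genes 28 (36.4%) were called higher in co_ton against 832 of 7543 other genes (11.0301%), with a one-sided Fisher's exact p = 6.54e-09 over genes, which are not independent. In co_ton 2 of the 77 fell, while in co_ment 32 rose and 16 fell (45 and 8 after TMM scaling). There 6 of 16 iron and siderophore genes fell and TMEN_9950 rose (2 and 2 after TMM scaling, 4 and 4 without ment_1). None of TMEN_9412, TMEN_6182, TMEN_9083 and TMEN_9950 fell. Their log2 fold changes were higher than in co_ton by 4.04, 3.11, 2.85 and 3.76 (limma adjusted p up to 0.000966). The explanation stays open. A rise of respiration genes alone would leave other iron-using genes unchanged. Yet 21 of the 55 outside the respiration list rose (38.2%, one-sided Fisher's exact p = 1.63e-07). TMEN_9412 also fell in co_int (-1.89). In co_ment it was at 37.1, 42.01 and 31.3 TPM against 74.7, 12.95 and 18.1 TPM in ment. Its comparison there rests on ment_1, as do those of TMEN_6182 and TMEN_9083.

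Genes at least 2-fold higher in co_ton tended to lie next to one another by identifier. Among 119 of them 14 pairs had consecutive identifiers, against a median of 2 and a maximum of 9 in 10000 random draws (one-sided permutation p = 1e-04, the smallest possible). The longest run was of 4 genes, TMEN_6312 to TMEN_6315, which holds the aminotransferase TMEN_6313 and the polyketide synthase TMEN_6315. The draws describe these runs, and no cause was tested. Runs in other comparisons were not counted. The secondary metabolism list had 2 of 30 higher and 0 lower in co_ton (camera adjusted p = 0.881). Identifiers stood in for position because no fungal genome was used here.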
